A study of Mus musculus with 12 samples.

How the data were processed

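RNA was measured by sequencing in 12 mouse libraries, 3 in each of 4 groups set by the submitters' labels. Per the labels' protocols, ILC2s were taken from lung, grown in IL-2, IL-7, IL-25 and IL-33 and then kept for 48 h with IL-2 and IL-7. Eosinophils came from blood as the fraction not held by beads against B220 and CD90 and were kept for 24 h with IL-33. Both were washed and cultured alone or together for 24 h without added cytokines, separated by flow cytometry and lysed in Trizol, and libraries were made with the NEBNext Ultra II kit. The labels give neither the number of cells per culture nor whether cells cultured alone also passed through the sorter.

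The values used are the authors' deposited read counts per gene, whole numbers with no normalization. The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.36, STAR 2.5.2b, featureCounts, Subread 1.5.2 and genome build mm10. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Without the strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart, and genes with near-identical copies (the Ear ribonucleases, Bcl2a1, hemoglobin, Csf2rb, Pira and Apol7 families) are uncertain.

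The table held 49315 genes by Ensembl identifier. GENCODE M21, on the same build, gave a symbol and position for 48970, and 66 symbols were carried by more than 1 identifier. The 345 others were kept under their identifier. Library totals were 16769929 to 22928961 counts. Replicates were not duplicates, since every pair differed beyond sampling noise (chi-square per degree of freedom 2.57 to 19.5 over genes with at least 20 counts in the pair).

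Each comparison was fitted in edgeR 4.0.16 on R 4.3.3 with filterByExpr, TMM scaling and the quasi-likelihood F test, without covariates. Cell type and coculture comparisons used the 6 libraries concerned, and the difference between the responses used all 12 libraries as (ILC2s with eosinophils minus alone) minus (eosinophils with ILC2s minus alone). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The standard error of a log2 fold change was its size divided by the square root of F. CPM values were scaled with TMM within a comparison, and partner RNA shares used CPM by library totals. The common biological coefficient of variation was 4.71% in ILC2s, 7.92% in eosinophils, 7.49% between cell types and 6.38% over all libraries.

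Gene lists (34 lists of 572 genes, 568 of them in the table) were fixed before the data were examined, as were the tests of genes and lists within a comparison, their alternatives and the rule for naming genes. The list tests of the difference of responses and the tests of glycolysis, hypoxia, Retnlg, Lyz2 and the part of each rise due to partner RNA were chosen later. Lists with at least 3 tested members were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusting over the lists of a comparison. Fry asks whether a list's genes move on balance one way and does not compare them with other genes. Named genes were, for each coculture comparison, the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 8 CPM and groups that did not overlap, leaving out of the rises those higher in the partner cell. They also included the 4 largest rises among genes higher in the partner cell, up to 4 members of each list by smallest p, and a fixed set (Il5, Il13, Il4, Il9, Csf2, Areg, Gata3, Il1rl1, Epx, Prg2, Siglecf, Ccr3, Il5ra and Cd274). The cell type comparison took 6 per side, and the difference of responses the 5 smallest p per side. Other genes in the text were chosen after their values were seen and went through the same alternatives.

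A gene counted as higher in the partner cell if its mean CPM there, alone or cocultured, exceeded that in the cocultured cell of interest. The partner RNA share was the median over markers of their CPM relative to the cocultured partner cell. Markers came from the fixed eosinophil list (19 kept) or lymphoid list (12 kept) and had at least 10 CPM in the partner and at most 1% of that in the cell of interest cultured alone. Shares were compared by an exact two-sided permutation test, and shared calls by Fisher's exact test.

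The fits were tested on simulated data, counts drawn from means pooled over the libraries of a comparison, with 200 genes changed. At 1.5-fold, 2-fold and 4-fold, 82.1%, 91.0% and 100% of changed genes were recovered over 14166 genes of the ILC2 comparison, and 68.7%, 88.1% and 100% over 12862 genes of the eosinophil comparison. The cell type comparison recovered 64.2%, 89.6% and 98.5% over 14162 genes, and the difference of responses 53.7%, 74.6% and 87.9% over 15105. False calls made up 4.71%, 5.0%, 8.20% and 3.36% of the calls. With no list changed but 1, camera called 0 of 27 other lists in the simulated ILC2 comparison and 0 of 31 in the eosinophil one. Genes were drawn independently of each other, so the simulation cannot show false list calls that correlation between genes would cause. It also changed far fewer genes than the real fits called (10454 of 14438 in ILC2s and 11719 of 14525 between cell types). It therefore cannot show recovery or false calls when most genes change, or for genes absent from 1 cell type.

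Alternatives were other scalings (DESeq2 size factors, upper quartile, library totals), other filters on low counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, a fit of all 12 libraries, subtraction of the estimated partner RNA, a 2-fold minimum, other marker sets and leaving out each library. All columns of the count table were used. Raw reads were not analysed here. Values of some genes that the rule would name, or that were chosen later, are not reported here.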

Results

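RNA-seq read counts per gene were compared for 12 mouse libraries in 4 groups of 3. Group 2 innate lymphoid cells (ILC2s) are tissue lymphocytes without antigen receptors that secrete type 2 cytokines when exposed to alarmins such as IL-33. Eosinophils are granulocytes of type 2 immunity that also carry the IL-33 receptor. The groups were lung ILC2s cultured alone, ILC2s cultured with eosinophils, blood eosinophils cultured alone and eosinophils cultured with ILC2s. All were kept for 24 h in medium without added cytokines after earlier culture with cytokines. Library totals ran from 16769929 to 22928961 counts, and 3 counts in a library corresponded to between 0.131 and 0.179 CPM (counts of a gene relative to the library total, on the usual scale). Values below are mean CPM ± SD over the n = 3 libraries of a group, scaled within each comparison, and log2 fold changes are given ± SE. The labels do not say that replicates were separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

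The comparison of both cell types cultured alone asked which transcripts belonged to which cell. The cells also differed in tissue of origin and in the cytokines given before, so a difference cannot be assigned to cell type alone. Each population carried the genes that define it. Gata3, the transcription factor of ILC2 identity, stood at 768 ± 8.39 CPM in ILC2s and 1.49 ± 0.721 CPM in eosinophils (log2 fold change 9.02 ± 0.14, edgeR adjusted p = 7.8e-17). Siglecf, an eosinophil surface lectin, stood at 1402 ± 9.76 CPM in eosinophils and 0.235 ± 0.0506 CPM in ILC2s (log2 fold change -12.54 ± 0.11, edgeR adjusted p = 6.1e-19). The eosinophil genes Ccr3 (-10.59), Prg2 (-12.66) and Il5ra (-10.23) were lower in ILC2s by log2 fold change. The IL-33 receptor gene Il1rl1 was expressed by both cells, at 2558 ± 51.2 CPM in ILC2s and 999 ± 28.3 CPM in eosinophils, and passed the test (log2 fold change 1.36 ± 0.053).

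Eosinophils cultured alone held more transcripts of 3 type 2 cytokines than ILC2s cultured alone. The eosinophils came from 24 h with IL-33 and the ILC2s from 48 h with IL-2 and IL-7. Cell type and pretreatment cannot be told apart here. The libraries of eosinophils alone also held some basophil and mast cell markers, such as Hdc (34.3 ± 3.99 CPM) and Fcer1a (3.80 ± 0.425 CPM, both scaled within the eosinophil coculture comparison). The median of the 11 such markers was 1.01 CPM by library totals. Whether other cells in the fraction added to the cytokine transcripts was not tested. Il5, the growth factor of eosinophils, stood at 1238 ± 36.9 CPM in eosinophils and 52.0 ± 0.762 CPM in ILC2s (log2 fold change -4.57 ± 0.063, edgeR adjusted p = 2.3e-17). Il13 (-2.18 ± 0.068) and Il4 (-3.75 ± 0.10) went the same way, whereas Csf2, which encodes GM-CSF, was higher in ILC2s (4.76 ± 0.22). Areg had 0 counts in eosinophils and 22 in ILC2s, at least 7.23-fold higher against a floor of 3 counts over the group. Il9 had 6 counts in eosinophils and 0 in ILC2s, 2.03-fold against that floor and too few for a lower bound.

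The genes with the largest differences included Tnfsf11 on the ILC2 side, at 0 counts in eosinophils and at least 1018-fold higher. Dach2, Ms4a6b and Apol7e, the last of a family of similar copies and so uncertain, also had 0 counts in eosinophils and were at least 789-fold, 649-fold and 1245-fold higher. Eya2 had 2 counts there, a ratio of 4771 (95% counting interval 1321 to 39405). On the eosinophil side stood the chemokine genes Ccl22, at least 1049-fold higher, and Ccl9, at 1029.6 ± 72.4 CPM in eosinophils and 0.104 ± 0.0387 CPM in ILC2s. Pira2, whose reads may be shared with near-identical paralogs, was at least 1345-fold higher. Cxcr2, Pstpip2 and Chst13 had 1, 3 and 2 counts in ILC2s, with ratios of 10334 (1854 to 408221), 6907 (2363 to 33494) and 7020 (1943 to 57969). Such intervals cover counting error only. Of 14525 genes tested, 5923 were higher in ILC2s and 5796 in eosinophils at an edgeR adjusted p under 0.05. Scaling by library totals moved the median of all genes by 0.57 and upper quartile scaling by 0.23 on the log2 scale, and with library totals the split was 8587 to 3664.

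The comparison of ILC2s cultured with and without eosinophils asked how eosinophils earlier kept with IL-33 change ILC2 gene expression. No group held eosinophils without that pretreatment, so an effect of eosinophils and one of their pretreatment cannot be told apart. ILC2s cultured with eosinophils held far more cytokine, cell cycle and glycolytic transcripts than ILC2s cultured alone. Il13, the cytokine that drives mucus production and alternative macrophage activation, rose from 37.5 ± 1.02 to 1175 ± 41.0 CPM (log2 fold change 4.97 ± 0.047, edgeR adjusted p = 1.7e-33). Il5 rose from 60.0 ± 0.703 to 395 ± 14.1 CPM (2.72 ± 0.042, edgeR adjusted p = 7.2e-29). All 24 tested DNA replication genes, 23 mitosis genes and 17 glycolysis genes rose. Of 14438 genes tested, 5315 rose and 5139 fell at an edgeR adjusted p under 0.05, with 2016 and 1428 beyond 2-fold.

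The list of type 2 cytokines and effector products, fixed before the data were examined like all lists here, had 9 members higher, 2 lower and 1 not past the threshold (camera adjusted p = 2.9e-18, and adjusted p = 0.043 with an estimated correlation). Il13 (ENSMUSG00000020383, chromosome 11, 53631324 to 53634702 on build mm10) and Il5 (ENSMUSG00000036117, chromosome 11, 53720794 to 53725106) lie in the type 2 cytokine cluster with Il4 (ENSMUSG00000000869, chromosome 11, 53602982 to 53618669). Il4 did not pass the test, at 8.24 ± 0.660 to 7.90 ± 1.07 CPM (edgeR adjusted p = 0.68). Lif, a cytokine of the IL-6 family, rose from 8.26 ± 0.466 to 791 ± 50.7 CPM (6.58 ± 0.062). Areg, an epidermal growth factor receptor ligand used in tissue repair, rose from 0.381 ± 0.152 to 16.0 ± 0.288 CPM (5.43 ± 0.21), and Csf2 from 14.4 ± 0.812 to 51.9 ± 3.20 CPM (1.85 ± 0.077). Also higher were Calca (3.56), which encodes the neuropeptide CGRP, the opioid precursor gene Penk (8.23), Il10 (7.56) and Il6 (3.11). The 2 lower members were Il2 (-3.31) and Tnfsf11 (-1.42). Il9 had 0 counts alone and 7 with eosinophils, 2.12-fold against the floor of 3 counts and too few for a lower bound, and was not tested. Il10, Il6, Il2 and Tnfsf11, and below other members of small groups, lie outside the fixed rule for naming genes and were named after their values were seen.

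**Figure D1:**
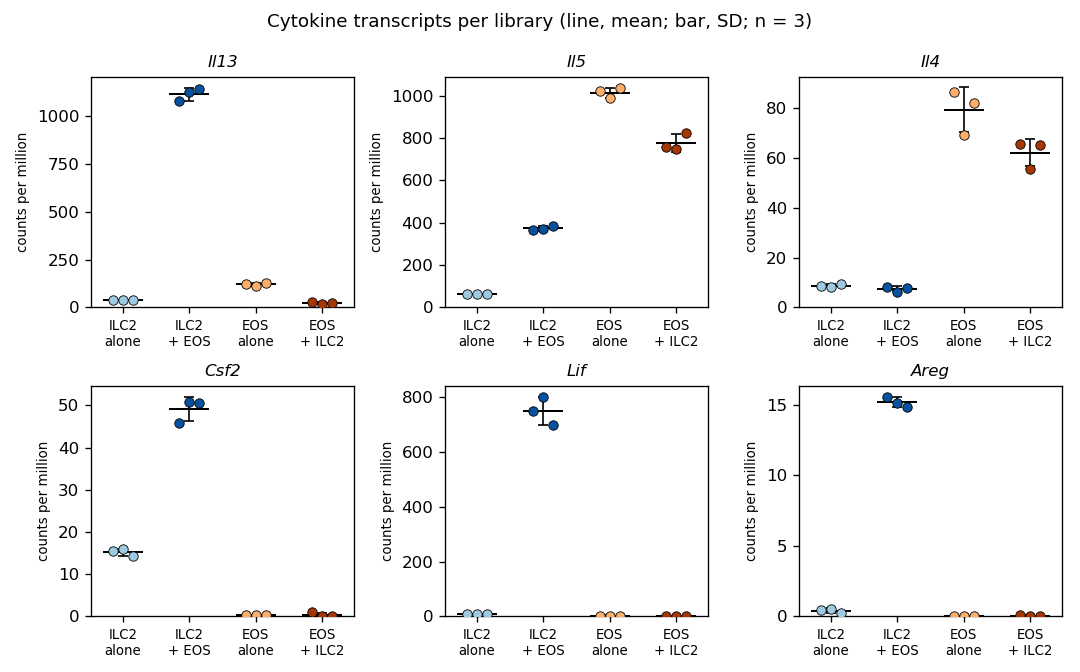
Cytokine transcripts in CPM (vertical axes, linear from 0) for each of the 12 libraries, scaled by library totals, in ILC2s and eosinophils (EOS) cultured alone or together. Points are libraries, lines the group means and bars the SD (n = 3), with Il13 rising in ILC2s (log2 fold change 4.97) and falling in eosinophils (-2.48).

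The 8 largest rises by the fixed rule included 3 receptor genes. Tnfrsf8, which encodes CD30, rose from 0.678 ± 0.515 to 575 ± 54.5 CPM (9.82 ± 0.12), and the decoy IL-1 receptor gene Il1r2 from 0.901 ± 0.472 to 379 ± 16.9 CPM (8.77 ± 0.098). Ctla4, a checkpoint receptor, rose from 0.534 ± 0.284 to 226 ± 17.6 CPM (8.64 ± 0.11). Irf4, a transcription factor of activated lymphocytes (ENSMUSG00000021356, chromosome 13, 30749226 to 30766976), rose from 1.94 ± 0.241 to 378 ± 22.1 CPM (7.59 ± 0.075, edgeR adjusted p = 3.5e-33). Msc (8.26) and Penk completed the group together with 2 genes nearly absent from ILC2s cultured alone. Mmp10, a matrix metalloproteinase gene, had 1 count alone and 2405 with eosinophils, a ratio of 2185 (95% counting interval 392 to 86334), and the prolyl hydroxylase gene P4ha3 had 3 and 1232, a ratio of 373 (127 to 1812). The 8 largest falls by the same rule, which asks for a mean of at least 8 CPM, were in Cpne7 (-5.27), Fbxl21 (-4.89), Rasgrp2 (-4.65), Tbc1d4 (-4.19), Slc26a11 (-4.00), Sgk1 (-3.93), Card6 (-3.73) and St3gal6 (-3.67). Rasgrp2, an activator of Rap GTPases, fell from 104 ± 0.892 to 4.13 ± 0.349 CPM and the kinase gene Sgk1 from 45.8 ± 2.91 to 3.00 ± 0.256 CPM.

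Cell cycle genes rose together. All 24 tested DNA replication genes were higher, among them Rrm2 (4.57 ± 0.061), a ribonucleotide reductase subunit, Mcm5 (4.12 ± 0.077) of the replicative helicase and Pcna (2.46 ± 0.044), the polymerase clamp (camera adjusted p = 1.4e-38, and adjusted p = 0.089 with an estimated correlation). All 23 tested mitosis genes were higher, including Ccna2 (3.68 ± 0.067), Top2a (3.24 ± 0.05) and Mki67, which rose from 126 ± 3.55 to 839 ± 72.5 CPM (2.73 ± 0.05), with camera adjusted p = 2.5e-57, and adjusted p = 0.079 with an estimated correlation. All 21 ribosome biogenesis and MYC target genes rose, among them Odc1 (1.83), Nop58 (1.45) and Npm1 (1.00), with camera adjusted p = 5.3e-09, and adjusted p = 0.26 with an estimated correlation. Transcripts of ribosomal proteins made up 5.34% ± 0.138 of counts in ILC2s alone and 7.33% ± 0.269 in ILC2s with eosinophils (SD, n = 3).

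Metabolic lists moved up as well. All 17 glycolysis genes rose, among them Tpi1 (4.11 ± 0.051), Gapdh (3.12 ± 0.038) and Pgk1, which went from 174 ± 7.57 to 1592 ± 52.8 CPM (3.20 ± 0.043), with camera adjusted p = 6.7e-38, and adjusted p = 0.079 with an estimated correlation. The lactate exporter gene Slc16a3 rose from 16.3 ± 1.34 to 304 ± 7.18 CPM and stood higher still in eosinophils. Of 17 hypoxia response genes 15 rose, including Vegfa (3.45 ± 0.079), Egln3 (2.93 ± 0.044) and Bnip3 (2.88 ± 0.059), Pdk1 fell (-0.24) and Nrn1 did not pass the test (camera adjusted p = 2.3e-10, and adjusted p = 0.19 with an estimated correlation). In oxidative phosphorylation 24 of 25 genes rose, for example Cycs (2.22) and Atp5b (1.28), and Ndufs3 did not pass (camera adjusted p = 7.7e-07, and adjusted p = 0.14 with an estimated correlation). In cholesterol synthesis 18 of 20 rose, such as Idi1 (3.04), and Sc5d fell (-0.50), with camera adjusted p = 4.2e-05, and adjusted p = 0.079 with an estimated correlation. A further cholesterol gene, Srebf2 (-0.08), counted as lower when adjusted over the list alone, with DESeq2 (adjusted p = 0.0399), limma-voom (0.0382), 2 other scalings and a CPM filter (edgeR, 3.0e-06 to 0.0384) and without either of 2 libraries (0.0245 and 0.0357). In the amino acid and ER stress response 17 of 20 rose, including Psat1 (2.68) of serine synthesis and the chaperone gene Hspa5 (1.80), while Ddit3 (-1.10) and Herpud1 (-0.35) fell (camera adjusted p = 5e-07, and adjusted p = 0.079 with an estimated correlation).

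Cytokine signalling genes changed in both directions. Of 14 STAT5 targets 10 rose, among them Socs3 (5.34 ± 0.088), Osm (2.45 ± 0.048), Il2ra (2.15 ± 0.04) and Cish (1.45 ± 0.04), and Bcl2 (-0.49) and Mcl1 (-0.20) fell (camera adjusted p = 5.3e-09, and adjusted p = 0.043 with an estimated correlation). Cytokine receptors had 9 higher, 11 lower and 5 not past the threshold (camera adjusted p = 0.0048, and adjusted p = 0.14 with an estimated correlation). Their call was also lost with the replicate block (camera adjusted p = 0.175). Il10ra (3.94), Csf2rb (3.66, uncertain because of its close copy Csf2rb2) and Il2rb (2.67) rose, and Il6ra fell (-3.68). Costimulatory and checkpoint genes had 15 higher and 6 lower of 23 (camera adjusted p = 0.0059, and adjusted p = 0.095 with an estimated correlation), with Pdcd1 (2.71), Cd69 (2.90) and Cd28 (1.71) higher and Icosl (-2.13) and Cd274 (-0.87) lower. Cd274, the gene of PD-L1, fell from 54.0 ± 2.31 to 29.6 ± 0.634 CPM. Of 9 genes of the IL-4 and IL-13 response of myeloid cells 8 rose (camera adjusted p = 0.0019, and adjusted p = 0.09 with an estimated correlation), among them Il4ra (0.89), and the call was lost without genes that eosinophils held at a higher level (camera adjusted p = 0.324). Ccl24 and Ccl22, also on the chemokine list, had 0 counts in ILC2s alone and 283 and 135 with eosinophils, at least 85.7-fold and 40.9-fold higher.

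Genes of ILC2 identity went both ways, with 8 higher, 14 lower and 2 not past the threshold of 24 (camera adjusted p = 0.18). Tcf7, a transcription factor of lymphoid progenitors, fell from 62.4 ± 2.98 to 8.43 ± 1.30 CPM (-2.89 ± 0.087), the IL-7 receptor gene Il7r fell from 1656 ± 14.3 to 282 ± 29.6 CPM (-2.55 ± 0.051), and Ets1 (-1.10) and Vipr2 (-2.08) also fell. Ccr8 (1.37) and Il2ra, the high-affinity IL-2 receptor subunit, rose. Gata3 stood at 887 ± 11.4 to 833 ± 19.1 CPM (log2 fold change -0.09 ± 0.036, edgeR adjusted p = 0.027), a fall that no longer passed without ILC2_alone replicate 3 or ILC2_with_EOS replicate 1 or 2, where the adjusted p ran from 0.0728 to 0.134, nor with no low-count filter (0.137) or in the fit of all 12 libraries (0.287). Il1rl1 did not pass the test (0.06 ± 0.036, edgeR adjusted p = 0.14), and with library totals alone its log2 fold change was -0.10 (edgeR adjusted p = 0.0135). It rose with no low-count filter (0.08, edgeR adjusted p = 0.0303) and without ILC2_with_EOS replicate 1 (0.11, edgeR adjusted p = 0.00705).

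Lists of other pathways were not called by camera in ILC2s, although some were under alternatives. Library totals alone called chemokines (camera adjusted p = 0.0437) and lymphoid markers (0.0289), and the replicate block called chemokines (camera adjusted p = 0.0414). Leaving out genes that eosinophils held at a higher level called lymphoid markers (camera adjusted p = 0.0266) and immediate early genes (0.00841). The interferon response had 6 higher and 9 lower of 18 (Mx1 4.24, Gbp3 1.66), NF-kB targets 9 and 6 of 20 (Ier3 3.06, Traf1 -0.76), and immediate early genes 9 and 4 of 18 (Egr1 4.15, Btg2 -1.82). Eicosanoid genes had 7 higher and 6 lower of 13 (Cysltr2 2.18, Hpgds -2.29), adhesion and migration 7 and 10 of 18 (Ccr1 3.81, Itgae -3.06), cell death 12 and 5 of 18 (Pmaip1 1.81, Bcl2l11 -2.05) and survival genes 5 and 4 of 11 (Bcl2l1 1.18, Bcl2 -0.49). Chemokines had 5 higher and 0 lower of 7 (Ccl5 2.80, Cxcl3 3.95), and MHC class II presentation 4 and 3 of 10 (Cd74 4.56, Ctss -0.91), or 4 and 4 adjusted over the list alone. Lymphoid markers had 5 higher and 14 lower of 20 (Ikzf3 1.53, Tcf7 -2.89).

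Markers of other cells were measured beside these groups. Of 24 eosinophil markers 5 could be tested in ILC2s, of which Pirb passed (1.18, but not with DESeq2, adjusted p = 0.0656, with no low-count filter, edgeR 0.0550, or without either of 2 libraries, 0.0675 and 0.0794, at 0.327 to 0.753 CPM, and 0 adjusted over the list alone), and no eosinophil granule gene could be tested, with Epx at 2 and 3 counts. The partner RNA share by 19 eosinophil markers, whatever the source of these traces, was 0.0311% ± 0.00332 in cocultured ILC2s and 0.0356% ± 0.0121 in ILC2s alone (SD, n = 3, exact two-sided permutation p = 0.6, where 0.1 is the smallest possible). The direction depended on the markers, since 239 wide markers gave 0.101% ± 0.0135 cocultured and 0.0837% ± 0.00678 alone (exact p = 0.1). Both marker sets were kept for low values in ILC2s alone, which favours a higher cocultured value. Of the 5315 genes that rose, 1108 stood at a higher level in eosinophils (5060 of all 14438 tested), and 4207 did not. The 4 largest rises among the former with a mean of at least 8 CPM were Cd74 (1.06 to 24.4 CPM), Adap1 (5.83 to 120.5 CPM), Ctsh (6.71 to 133 CPM) and Slc16a3. B cell markers had 3 higher and 2 lower of 5 (Cd22 4.13, Ighm -1.40, and Fcmr with 3 and 100 counts, a ratio of 30.3 with interval 10.1 to 149). T cell receptor genes had 3 and 2 of 6 (Cd3d 1.19, lost without any of 3 libraries, edgeR adjusted p 0.0617 to 0.0941, Trbc2 -0.61), monocyte markers 1 and 1 of 3 (Cx3cr1 1.79, Ccr2 -0.85) and basophil and mast cell markers 0 and 2 of 3 (Cpa3 -1.52, Cd200r3 -0.90). Of lists with fewer than 3 tested members, Hba-a1 rose (0.463 to 17.0 CPM, uncertain because of its copy Hba-a2), as did the NK cell gene Prf1 (1.21), Mpo had 3 and 171 counts (ratio 51.8, interval 17.4 to 254), and Mmp9 (-3.51) and the platelet genes Itga2b (-1.59) and Gp1ba (-0.78, lost without ILC2_with_EOS replicate 2, edgeR adjusted p = 0.0816) fell.

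Among the 13 lists camera called in ILC2s, all upward, 2 held with an estimated correlation, type 2 cytokines and STAT5 targets. The rotation test fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, called 27 of 29. The median, mean and camera direction differed in sign for 8 of the 29 lists, none of them called by camera. Counts adjusted over the list alone equalled those over all genes except for the 3 lists named. Scaling by library totals moved the median of all genes by -0.16 on the log2 scale and gave 4385 higher and 6330 lower genes.

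The comparison of eosinophils cultured with and without ILC2s asked how ILC2s earlier kept with cytokines change the gene expression of eosinophils earlier kept with IL-33. Here too no group held cells without their pretreatment. Eosinophils cultured with ILC2s lost transcripts of glycolysis, of the hypoxia response and of cytokine signalling through STAT5, and gained others. Vegfa, the angiogenic growth factor gene induced by low oxygen, fell from 147 ± 12.2 to 8.91 ± 1.78 CPM (-4.04 ± 0.12, edgeR adjusted p = 2.8e-11). Retnlg, a secreted resistin-like factor gene, rose from 98.1 ± 13.7 to 631 ± 44.1 CPM (2.69 ± 0.093, edgeR adjusted p = 1.6e-10). Of 13109 genes tested, 1493 rose and 1771 fell at an edgeR adjusted p under 0.05, with 151 and 604 beyond 2-fold. Without EOS_with_ILC2 replicate 3 the number that rose was 948. The split was 2114 to 1532 with library totals alone and 2276 to 1958 in the fit of all 12 libraries.

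All 17 glycolysis genes fell, among them Pfkl (-2.76 ± 0.058), Tpi1 (-2.63 ± 0.059), Pfkp (-2.28 ± 0.068) and Pgk1, which went from 989 ± 13.4 to 189 ± 6.82 CPM (-2.39 ± 0.055), with camera adjusted p = 7.2e-87, and adjusted p = 0.0017 with an estimated correlation. Of 14 hypoxia response genes 13 fell and Car9 did not pass the test (camera adjusted p = 4.9e-91, and adjusted p = 0.0017 with an estimated correlation). Egln3, a prolyl hydroxylase gene induced by low oxygen (ENSMUSG00000035105, chromosome 12, 54178981 to 54203860), fell from 438 ± 3.39 to 36.8 ± 0.859 CPM (-3.57 ± 0.059), Bnip3 from 232 ± 17.3 to 22.7 ± 2.40 CPM (-3.35 ± 0.087) and Ndrg1 from 37.2 ± 8.09 to 2.97 ± 0.618 CPM (-3.64 ± 0.18). The other large falls by the fixed rule were Stc2 (-5.63), the endothelial lipase gene Lipg (-4.10, from 411 ± 8.40 to 24.0 ± 1.87 CPM), Neb (-3.48) and the aldolase gene Aldoc (-3.43).

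STAT5 targets, which IL-5 and GM-CSF induce in eosinophils, fell for 14 of 15 genes, and Socs2 did not pass the test (camera adjusted p = 3.9e-45, and adjusted p = 0.011 with an estimated correlation). Cish fell from 780.2 ± 3.73 to 261 ± 10.0 CPM (-1.58 ± 0.053) and Pim1 from 1790.3 ± 98.9 to 622 ± 62.7 CPM (-1.52 ± 0.072), and Osm (-2.02), Socs1 (-1.79) and Socs3 (-1.61) also fell. Survival genes had 8 lower, 1 higher and 3 not past the threshold of 12 (camera adjusted p = 4.5e-12, and adjusted p = 0.012 with an estimated correlation), with Bcl2 (-1.44 ± 0.086) and Bcl2l1 (-1.07 ± 0.06), both anti-apoptotic, lower, and Birc3 (0.62) higher. Bcl2a1d also fell (-1.08) but shares reads with near-identical copies and is uncertain. Cell death genes had 6 higher and 3 lower of 16 and were not called by camera, with Cdkn1a (-2.13) among the lower.

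Type 2 cytokine transcripts in eosinophils fell for 4 of 5 tested genes (camera adjusted p = 3e-05, and adjusted p = 0.14 with an estimated correlation). Il13 fell from 123 ± 7.39 to 22.1 ± 3.93 CPM (-2.48 ± 0.11, edgeR adjusted p = 1.2e-09), Il5 from 1036 ± 28.8 to 763 ± 43.7 CPM (-0.44 ± 0.056, edgeR adjusted p = 5.1e-05), Il4 from 81.0 ± 9.10 to 61.0 ± 5.62 CPM (-0.41 ± 0.09) and Lif from 2.78 ± 0.732 to 0.260 ± 0.0689 CPM (-3.39 ± 0.39), while Il6 did not pass. Basophil and mast cell markers fell in the same libraries, as given below. Of 18 immediate early genes 14 fell and 2 rose, with Fos (-2.48) and Junb (-0.77) lower and Egr2 (0.82) and Btg2 (0.35) higher (camera adjusted p = 2.5e-06, and adjusted p = 0.085 with an estimated correlation). The IL-4 and IL-13 response of myeloid cells had 11 lower and 2 higher of 17, or 12 and 4 adjusted over the list alone (camera adjusted p = 3e-06, and adjusted p = 0.21 with an estimated correlation). The chemokine genes Ccl22 (-2.46) and Ccl17 (-2.44) and Il4ra (-1.18) were lower there, and Fn1 (1.91) and Alox15 (0.59), a lipoxygenase gene, higher.

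Costimulatory and checkpoint genes had 8 lower and 1 higher of 15, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.00093, and adjusted p = 0.085 with an estimated correlation), with Tnfsf9 (-2.45) and Cd274 (-1.29 ± 0.069) lower and Cd101 (1.58 ± 0.086) higher. Cytokine receptors had 7 lower and 5 higher of 26, or 8 and 7 adjusted over the list alone (camera adjusted p = 0.029, and adjusted p = 0.21 with an estimated correlation), and the call was lost with library totals alone (camera adjusted p = 0.0544) and without EOS_with_ILC2 replicate 1 (0.0706) or 2 (0.0604). Il1r2 (-3.12), Il18rap (-1.93) and Il1rl1, which went from 836 ± 25.4 to 535 ± 11.9 CPM (-0.64 ± 0.052), fell, and Il1rn, Tgfbr1, Il21r, Il17ra and Csf2ra rose. Csf2ra lost its call without any of 5 libraries (edgeR adjusted p 0.0554 to 0.105). In the amino acid and ER stress response 9 fell and 1 rose of 20, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.0012, and adjusted p = 0.21 with an estimated correlation), with Xbp1 (-1.70) lower and Slc3a2 (0.88) higher. Basophil and mast cell markers fell for 4 of 6 genes (camera adjusted p = 8.5e-05, and adjusted p = 0.075 with an estimated correlation), namely Cd200r3 (-1.67), Hdc (-1.29), Fcer1a (-1.21) and Gata2 (-0.99), and Cpa3 and Ms4a2 did not pass.

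Eosinophil markers were the 1 list called upward, with 10 higher and 5 lower of 22, or 12 and 5 adjusted over the list alone (camera adjusted p = 0.021, and adjusted p = 0.45 with an estimated correlation). The call was lost without EOS_alone replicate 2 (adjusted p = 0.0628). Il5ra, the IL-5 receptor gene (ENSMUSG00000005364, chromosome 6, 106710357 to 106749037), rose from 122 ± 5.77 to 195 ± 5.91 CPM (0.68 ± 0.059), the eotaxin receptor gene Ccr3 from 1340.2 ± 37.6 to 1763 ± 26.0 CPM (0.40 ± 0.048), and Alox15 from 3954 ± 223 to 5932 ± 93.8 CPM. Siglecf (-0.03 ± 0.047, edgeR adjusted p = 0.73) and the granule gene Prg2 (-0.08 ± 0.071, edgeR adjusted p = 0.46, and -0.17 with 0.0329 without EOS_alone replicate 2) did not pass the test, and Epx, eosinophil peroxidase, lay at the threshold (0.33 ± 0.11, edgeR adjusted p = 0.0501), which it passed with library totals alone (0.0227), with partner RNA subtracted (0.0490) and without EOS_with_ILC2 replicate 1 (0.0352). The ribonuclease genes Ear1 (1.48) and Ear2 (1.19) were higher and Ear6 (-1.25) lower, but these copies can share reads and their direction is uncertain. The other lower members were Itgam, Mgst1, Cd300lf and Adgre1. Granule proteins as a list had 2 higher and 1 lower of 7, or 3 and 1 adjusted over the list alone, and were not called.

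The largest rises by the fixed rule were Cd34 (5.12 ± 1.12 to 47.8 ± 11.0 CPM, 3.23 ± 0.18), a stem cell and eosinophil sialomucin gene, Retnlg and the lysozyme gene Lyz2 (10.4 ± 2.57 to 64.3 ± 4.61 CPM, 2.62 ± 0.13). Pbld2 (2.25), Zfyve28 (2.10), the retinoid enzyme gene Dhrs3 (1.91) and the metalloproteinase genes Mmp12 (1.80) and Mmp27 (1.77) followed. Adhesion and migration genes had 8 higher and 5 lower of 21, or 9 and 7 adjusted over the list alone, and were called by fry (adjusted p = 0.00125) and by camera without EOS_with_ILC2 replicate 1 (camera adjusted p = 0.0489) or 3 (0.0354), but not by camera with all libraries. The chemokine receptor gene Cxcr4 (1.69 ± 0.077) and the integrin genes Itgax (1.41 ± 0.066) and Itgal (1.09) were higher. Sntb1 (3.28), Atp10a (2.75), Spata13 (2.07) and Lgmn (1.93) were the 4 largest rises with a mean of at least 8 CPM among genes that ILC2s held at a higher level. Such genes made up 827 of the 1493 that rose and 9088 of all 13109 tested.

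The partner RNA share by 12 lymphoid markers, whatever the source of these traces, was 0.0842% ± 0.0305 in cocultured eosinophils and 0.146% ± 0.0516 in eosinophils alone (SD, n = 3, exact two-sided permutation p = 0.2, where 0.1 is the smallest possible). Lymphoid markers had 2 higher and 3 lower of 7 (Ets1 0.52, Klrg1 -0.86), and ILC2 identity genes 3 and 8 of 17, or 3 and 9 adjusted over the list alone. Neutrophil markers had 3 higher and 3 lower of 10, with Retnlg, Mmp8 (2.16) and Mmp9 up and S100a8 (-1.79), S100a9 and Cxcr2 (-0.88) down. Mmp9 lost its call without any of 4 libraries (edgeR adjusted p 0.0530 to 0.139). Monocyte markers had 2 and 2 of 7, or 2 and 3 adjusted over the list alone, with Lyz2 and Adgre4 up and Ly6c2 (-1.13) and Fcgr1 (-1.01) down. B cell markers had 0 and 1 of 4 (Cd22 -1.35, lost with DESeq2, adjusted p = 0.0547, and without any of 5 libraries, edgeR adjusted p 0.0648 to 0.0941), or 2 and 1 adjusted over the list alone, platelet markers 1 and 1 of 4 (Ppbp 2.62, Gp1ba -0.67, lost without any of 3 libraries, 0.0563 to 0.0934), and Cd3d, the T cell receptor gene tested, did not pass (-0.74) but counted as lower over its list alone, with limma-voom (adjusted p = 0.0393) and without EOS_with_ILC2 replicate 1 (edgeR, 0.0203). No NK cell or erythroid marker reached the count filter.

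Growth lists showed few changes in eosinophils, and camera called neither them nor the other lists of this paragraph. Fry called mitosis (adjusted p = 0.0216), NF-kB targets (0.00812) and the interferon response (0.0320). DNA replication had 1 higher (Mcm7) and 1 lower (Ccne1) of 22, or 0 and 1 adjusted over the list alone, and mitosis the same counts of 15 (Cdc20 and Bub1). Mki67 (-0.30 ± 0.13, edgeR adjusted p = 0.12) did not pass but was lower with no low-count filter (edgeR adjusted p = 0.00904) and without EOS_alone replicate 3 (0.0318). Cdc20 lost its call with DESeq2 (adjusted p = 0.0966), limma-voom (0.0544), no low-count filter (0.0803) or partner RNA subtracted (0.0686) and without any 1 library (0.0508 to 0.182), and Mcm7 without any of 4 libraries (0.0645 to 0.0839). Ribosome biogenesis had 4 and 3 of 20 (5 and 3 over the list alone), cholesterol synthesis 2 and 5 of 20 (3 and 5) and oxidative phosphorylation 3 and 2 of 25 (2 and 2). NF-kB targets had 8 higher and 9 lower of 22 (9 and 9 over the list alone), with Tnfaip2 (0.97) up and Ier3 (-2.32) down, and chemokines 1 and 5 of 11 (2 and 6), with Ccl5 (1.13) up and Ccl3 (-0.81) down. Interferon response genes had 3 and 3 of 15 (Zbp1 -1.18 among the lower), eicosanoid genes 3 and 3 of 15 (Ptger2 1.30, Ptgs1 -0.68) and MHC class II presentation 2 and 1 of 11 (Ctss 1.22, H2-Ab1 -1.06).

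Of the 12 lists camera called in eosinophils, 11 were downward, and glycolysis, hypoxia response, STAT5 targets and survival genes held with an estimated correlation. The test fry called 18 of 31, and the median, mean and camera direction differed in sign for 7 of 31 lists, none of them called by camera. Outside genes that ILC2s held at a higher level, 666 genes rose. Without genes that ILC2s held at a higher level 6 lists were called, and eosinophil markers, the IL-4 and IL-13 response (camera adjusted p = 0.0584 for both), cytokine receptors (0.179) and costimulatory and checkpoint genes (0.825) were not, while the hypoxia response and type 2 cytokines had fewer than 3 genes left.

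**Figure D2:**
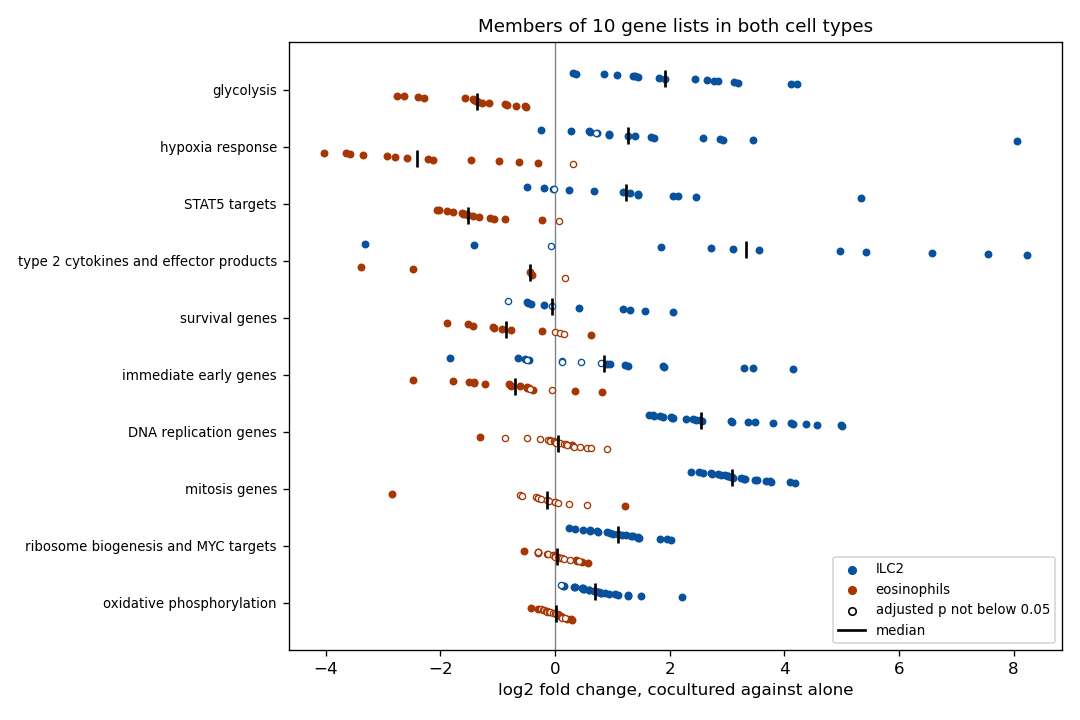
Log2 fold change, cocultured against alone (horizontal axis), for every tested member of 10 gene lists in ILC2s (blue) and eosinophils (brown). Points are genes, open points did not pass the test, black lines are medians, and all 17 glycolysis genes lie above 0 in ILC2s and below 0 in eosinophils.

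The last comparison asked whether coculture acted differently on the 2 cell types. More genes rose in one cell and fell in the other than independent lists would share. Still, most of the 4477 genes tested in both that rose in ILC2s were not among those that fell in eosinophils. Among 11963 genes tested in both, 789 rose in ILC2s and fell in eosinophils where independent lists would share 562 (Fisher's exact test, odds ratio 2.03, adjusted p = 2.6e-36), and 666 fell in ILC2s and rose in eosinophils where 512 would be shared (odds ratio 1.69, adjusted p = 2.6e-19). Fewer than that moved the same way, with 458 higher in both against 516 (odds ratio 0.813, adjusted p = 6.6e-04) and 390 lower in both against 558 (odds ratio 0.554, adjusted p = 2.8e-22). These comparisons share no libraries, and genes are not independent replicates.

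In a model of all 12 libraries, 8114 of 15745 genes had a response that differed between the cell types, 4215 with the larger value in ILC2s and 3899 in eosinophils (3357 and 5112 with library totals alone, which moved the median of all genes by -0.19). The 5 genes with the smallest p on the ILC2 side were Egln3, Cyp11a1, Pgk1, Il1r2 and Il13. Il13 had a difference of the 2 log2 fold changes of 7.43 ± 0.12 (edgeR adjusted p = 3.1e-23), since it rose in ILC2s and fell in eosinophils, and Il5 one of 3.14 ± 0.077. Egln3 (6.48 ± 0.077), Pgk1 (5.57 ± 0.077) and Il1r2 (11.86 ± 0.17) likewise rose in ILC2s and fell in eosinophils. Cyp11a1, which encodes the enzyme that starts steroid synthesis from cholesterol, had a difference of 6.69 ± 0.081. On the eosinophil side stood Csf1 (-3.53 ± 0.087), Rasgrp2 (-4.26 ± 0.11), Lpcat2 (-3.34 ± 0.088), Cd101 (-4.23 ± 0.12) and Sgk1 (-4.22 ± 0.13). Csf2 (1.98 ± 0.69), Gata3 (2.11 ± 0.36), Il1rl1 (0.68 ± 0.069) and Cd274 (0.40 ± 0.089) also differed, although Csf2 and Gata3 stood below 2 CPM in eosinophils and Csf2 lost its call without EOS_alone replicate 1 or 3 or EOS_with_ILC2 replicate 2 (edgeR adjusted p 0.0506 to 0.0559). Csf2 also lost its call with DESeq2 (adjusted p = 0.105), and Cd274 with library totals alone (edgeR adjusted p = 0.0559). Epx, Prg2, Siglecf, Ccr3 and Il5ra did not pass this test, and with partner RNA subtracted Il5ra (-1.97, edgeR adjusted p = 0.0422) and Siglecf (-5.20, edgeR adjusted p = 1.4e-05) did. That subtraction was made in cocultured libraries only, although the share in ILC2s alone was similar (0.0356% against 0.0311% cocultured). It can itself make these calls, which are therefore not read as responses. Il4 did not pass (edgeR adjusted p = 0.094) but did without ILC2_with_EOS replicate 2 (0.0305) or EOS_alone replicate 2 (0.0135). For Areg, with 0 counts in eosinophils alone, edgeR gave no usable estimate (2.58 ± 9.51), while DESeq2 (3.71, adjusted p = 0.0415) and limma-voom (4.80, adjusted p = 1.7e-04) called it.

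**Figure D3:**
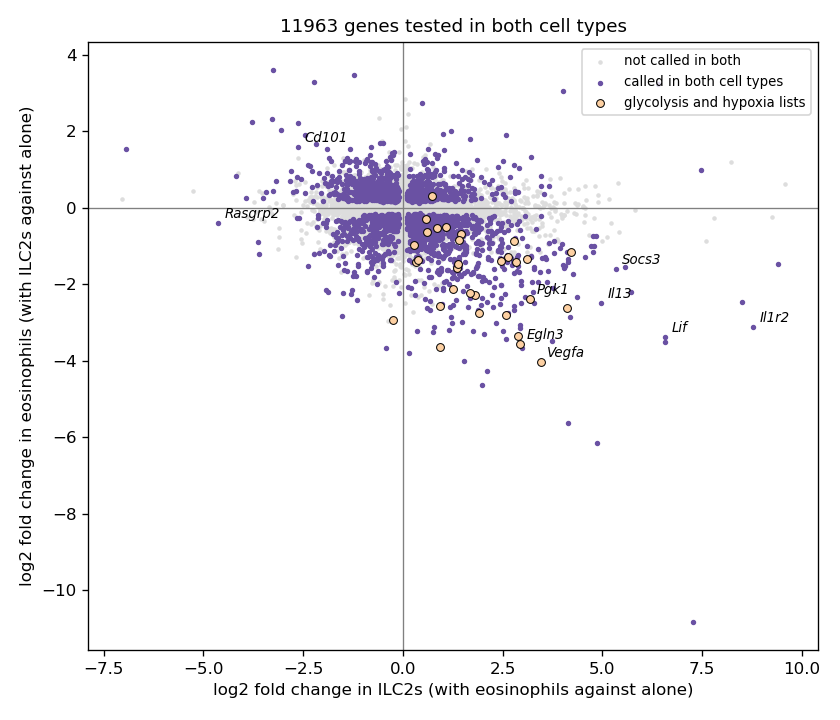
Log2 fold change in eosinophils (vertical axis) against log2 fold change in ILC2s (horizontal axis), each cocultured against alone, for 11963 genes tested in both. Purple points passed the test in both cell types, grey points did not, outlined points belong to the glycolysis and hypoxia lists, and 789 genes rose in ILC2s and fell in eosinophils.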

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

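Of the tests in this part, the list tests of the difference between the cell types, the share of each rise that partner RNA accounts for, and all tests on glycolysis, hypoxia, Retnlg and Lyz2 were chosen after the results were seen. The partner marker ratios and the splits of the libraries were set before.

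The response to coculture differed between ILC2s and eosinophils by a test of the difference itself for 8114 genes. Of 100 regroupings drawn from 200 possible ones, 1, the real one, gave that many. Regrouping also breaks up the effect of coculture within each cell type, so it cannot test the difference of responses alone. Replicates may be technical, so chance between cultures is not excluded. The highest other gave 7692 and kept the split of both cell types, with the alone and cocultured labels of the eosinophils exchanged. Those that kept only the ILC2 split gave 5623 to 6625 genes, and those that kept only the eosinophil split 108 to 162. The 75 that kept neither cell type's labels gave 0 by edgeR and at most 427 at an unadjusted p under 0.05. In the comparisons of 3 against 3, 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real values were 10454 in ILC2s, 3264 in eosinophils and 11719 between the cell types, where the highest other split gave 0 by edgeR, with at most 73, 720 and 27 at an unadjusted p under 0.05. These other splits mix the real groups, so the real difference counts there as spread within groups and pushes their counts down. Their low counts, and those of the 75 regroupings above, therefore do not measure how many false calls the real split holds.

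Named genes met this test with log2 differences (ILC2s minus eosinophils) of 11.86 for Il1r2, 7.43 for Il13, 6.69 for Cyp11a1, 6.48 for Egln3, 5.57 for Pgk1, 3.14 for Il5, 2.11 for Gata3, 1.98 for Csf2, 0.68 for Il1rl1 and 0.40 for Cd274. On the other side were Rasgrp2 at -4.26, Cd101 at -4.23, Sgk1 at -4.22, Csf1 at -3.53 and Lpcat2 at -3.34. Cd274 fell in both cell types and lost its call with library totals alone (edgeR adjusted p = 0.0559). Csf2 lost its call with DESeq2 (adjusted p = 0.105) and without any of 3 libraries (edgeR adjusted p 0.0506 to 0.0559). Gata3 in eosinophils is a trace, at 1.25 and 0.264 CPM, and serves as a lymphoid marker for the partner share.

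Lists whose response differed, all with the larger value in ILC2s, had camera adjusted p = 2e-111 for glycolysis, 4e-49 for the hypoxia response, 2e-30 for STAT5 targets, 1.7e-19 for DNA replication, 2.3e-08 for mitosis and 2e-09 for type 2 cytokines. Also called were the amino acid and ER stress response (camera adjusted p = 5.6e-09), cholesterol synthesis (8.5e-06), cytokine receptors (5.2e-05) and survival genes (9.6e-05). A further 4 lists lost their call with an estimated correlation, namely ribosome biogenesis (camera adjusted p = 1.5e-06, then 0.16), oxidative phosphorylation (1.2e-05, then 0.44), the IL-4 and IL-13 response (2.2e-05, then 0.15) and immediate early genes (0.0024, then 0.11). Cytokine receptors had a median of -0.09 and a mean of 1.09, so their median and test differed in sign. They also lost their call with the replicate block (camera adjusted p = 0.127).

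Of the genes that rose, 1108 of 5315 in ILC2s and 827 of 1493 in eosinophils stood higher in the partner cell. Of all genes tested, 5060 of 14438 and 9088 of 13109 did, a larger share in both. By definition a rise takes genes out of this class, so the shares cannot test carry-over. For the genes in the class, RNA carried through the sort is a candidate source. At the marker share it accounts for a median of 0.247% (interquartile range 0.123 to 0.563) of the rise of such genes in ILC2s and 0.676% (0.491 to 1.06) in eosinophils, against a bound of 10%, and for 2.94% and 4.83% at the highest share of any marker (in ILC2s Epx, on 3 counts in all). At the marker share it could make 50% of the rise for 7 genes in ILC2s and 0 in eosinophils, and at the highest share for 47 and 9. The source of the traces themselves cannot be told apart, because the quartiles of the marker ratios lay 2.65-fold apart for eosinophil markers (95% bootstrap interval 1.66 to 5.31) and 4.46-fold for lymphoid markers (1.68 to 14.3), and both intervals cross the bound of 3-fold. Cells cultured alone held such traces as well (mean share alone and cocultured 0.0356% and 0.0311% in ILC2s, 0.146% and 0.0842% in eosinophils), and the wide markers gave 0.0837% and 0.101% in ILC2s and 0.437% and 0.365% in eosinophils, but markers kept for low values in cells alone cannot test transfer, and a source common to all libraries stays open.

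Glycolysis and hypoxia genes rose in ILC2s and fell in eosinophils. Scaling between groups does not account for this, since 29 of 31 members tested in both cells were called in opposite directions under each of 4 scalings, and against genes of the same GC content and length class the 34 members kept 103% of their median log2 difference (3.73, then 3.83). Eosinophils among the sorted ILC2s would need a median share of 53.7% (interquartile range 31.4 to 87.8), while the highest eosinophil marker reached 0.371% (Epx, on 3 counts in all) and the next 0.0963% (Pirb). A response to the partner cell, for example to cytokines passed between them, stays open as a hypothesis, as does a difference in oxygen or nutrients if cell numbers per culture differed, which the labels do not give. Whether cells cultured alone also went through the sorter is likewise not stated.

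Retnlg and Lyz2, a neutrophil and a monocyte marker, rose in cocultured eosinophils, so other leukocytes in the sorted cells might be a source. The 12 other neutrophil markers that started at or below Retnlg changed in sum by -4.36 CPM (-7.13 to -1.59 at 2 standard errors), from 17.6 to 13.3, while Retnlg went from 96.0 to 642 CPM, and the bound set for neutrophils was 54.6, 0.1 of the rise of Retnlg. The 11 other monocyte and macrophage markers that started at or below Lyz2 changed in sum by -1.79 CPM (-3.86 to 0.272), from 19.1 to 17.3. The bound was 5.52, for a rise of Lyz2 from 10.2 to 65.4 CPM. Markers that started above Lyz2 were left out of that sum. Of these, Adgre4 rose from 509 ± 35.7 to 642 ± 9.58 CPM (scaled within the comparison), by more than the bound. Ly6c2 (42.3 to 19.4 CPM) and Fcgr1 (29.9 to 14.8 CPM) fell. Cxcr2, which fell, and Mmp9, which rose, were likewise left out of the neutrophil sum. Both sums count against cells that carry the summed markers as the whole source, but the markers left out went both ways. Genes off the lists that also rose, such as Mmp12 and Gpnmb, were not in the sums, so the result depends on the markers listed. A change of both genes within eosinophils remains a hypothesis found and tested on the same data.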

How the results depend on the processing

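Of the tests below, the list tests of the difference of responses and their alternatives were chosen after seeing the data, as were some of the named genes. Of 202 alternative values of counts and shares 181 stayed within 1.5 times or 1 SD of the value reported and 21 moved. Of 777 list results 705 kept their side of the threshold, 38 gained a call and 34 lost it. Of 6087 named gene results 5984 kept theirs, 45 gained a call, 56 lost it and 2 changed sign with a call. The overlap limited to genes higher in the partner of neither cell could not be run. By the definition only genes at exactly equal levels could qualify, and 0 of the 11963 genes remain. Requiring 2-fold left 2016 and 1428 genes higher and lower in ILC2s (1687 higher outside genes the partner held higher), 151 and 604 in eosinophils (89 outside), 3687 and 3309 between cell types and 3557 for the difference of responses, by construction. A mean of at least 8 CPM left 3654 genes higher in ILC2s than in eosinophils, also by construction. A fit of all 12 libraries called 2276 genes higher in eosinophils with ILC2s, and library totals alone 3664 genes higher in eosinophils than ILC2s, and for both the cause was not tested. Lists called fell to 2 in ILC2s and 4 in eosinophils with an estimated correlation, rose to 27 in ILC2s and 23 for the difference with fry, which tests another question, and fell to 6 in eosinophils without genes the partner held higher, where fewer genes are tested. The wide marker set gave partner shares of 0.101% in ILC2s (0.0837% alone, exact permutation p = 0.1) and 0.365% in eosinophils (0.437% alone, exact permutation p = 0.3), and the sum over markers 0.0378% in ILC2s, and the cause was not tested. The sign changes were Il1rl1 in ILC2s with library totals alone (log2 fold change -0.10) and the difference of responses for Siglecf with partner RNA subtracted (-5.20), where Siglecf had under 0.3 CPM in ILC2s. That subtraction was made in cocultured libraries only and can itself make the Siglecf change. Leaving out 1 library gave 5144 to 5297 higher and 4869 to 5141 lower in ILC2s (4085 to 4194 outside genes the partner held higher), 948 to 1604 and 1337 to 1923 in eosinophils (479 to 701 outside), 5717 to 6086 and 5662 to 5875 between cell types, 7656 to 8277 for the difference, 13 lists in ILC2s, 11 to 13 in eosinophils, and shares of 0.0298% to 0.0330% in ILC2s and 0.0673% to 0.0969% in eosinophils. The lowest eosinophil count came without EOS_with_ILC2 replicate 3. Replicate numbers did not consistently pair the samples. Same-numbered libraries correlated at 0.0298 to 0.322 (mean 0.146) between the eosinophil groups and -0.0128 to 0.0255 between the ILC2 groups. EOS_alone replicate 3 correlated best with EOS_with_ILC2 replicate 1 (0.211 against 0.0862). Partial pairing in eosinophils stays open. With the replicate block the counts were 5318 and 5104 in ILC2s (4213 outside), 2029 and 2139 in eosinophils (846 outside), 5865 and 5724 between cell types and 8150 for the difference, with 13, 12 and 14 lists. Under it cytokine receptors were not called in ILC2s (camera adjusted p = 0.175) or for the difference (0.127), chemokines were (0.0414 and 0.0243), and edgeR called Mki67 (0.00467), Epx (0.0379) and Cd3d (0.0267) in eosinophils and Il4 for the difference (0.0235). Genes under about 3 counts per library, 0.131 to 0.179 CPM, are not measurable at this depth.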

Other observations

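The genes in this part were chosen after their values were seen, and no explanation is offered for them. No gene group was tested with them. In ILC2s cultured with eosinophils, 4 transcription factor genes rose and 2 fell, as picked here. Myb rose from 0.312 ± 0.223 to 54.6 ± 5.91 CPM (log2 fold change 7.49 ± 0.18), Prdm1 from 9.41 ± 0.445 to 123 ± 6.00 CPM (3.70 ± 0.066), Nfil3 from 14.3 ± 1.06 to 149 ± 3.82 CPM (3.39 ± 0.059) and Batf from 27.3 ± 2.22 to 222 ± 5.76 CPM (3.03 ± 0.051), while Lef1 fell from 44.3 ± 4.02 to 11.7 ± 1.02 CPM (-1.92 ± 0.087) and Bach2 from 3.52 ± 0.318 to 0.798 ± 0.220 CPM (-2.12 ± 0.28). Tph1, the enzyme of serotonin synthesis, went from 5.37 ± 0.472 to 185 ± 6.66 CPM (5.09 ± 0.066), and Cyp11a1, which makes pregnenolone, from 34.5 ± 1.87 to 714 ± 18.0 CPM (4.37 ± 0.048). In eosinophils Cyp11a1 fell from 300.0 ± 9.16 to 59.3 ± 2.07 CPM (-2.34 ± 0.06). The metallothionein genes Mt1 (4.04) and Mt2 (4.40) and the triglyceride enzyme gene Dgat2 (4.82) rose in ILC2s, each with edgeR adjusted p no higher than 7.1e-19.

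In eosinophils cultured with ILC2s, the acid phosphatase gene Acp5 rose from 64.4 ± 6.26 to 168 ± 23.2 CPM (1.39 ± 0.096), Ctsd from 817 ± 68.3 to 1062 ± 71.6 CPM (0.38 ± 0.069) and Gpnmb from 1.94 ± 1.29 to 13.7 ± 1.10 CPM (2.84 ± 0.28), with Ctss (1.22) and Lgmn (1.93) also higher. Of these, Ctss and Lgmn stood at a higher level in ILC2s. The interleukin 1 receptor antagonist gene Il1rn rose from 737 ± 27.6 to 1412 ± 142 CPM (0.94 ± 0.069) while the decoy receptor gene Il1r2 fell from 77.6 ± 7.79 to 8.93 ± 0.607 CPM. Mgarp, which encodes a mitochondrial protein, had 655 counts in eosinophils alone and 0 with ILC2s, at least 233-fold lower against a floor of 3 counts over the group, and it rose in ILC2s (7.27 ± 0.27). The mitochondrial adenylate kinase gene Ak4 fell in eosinophils from 14.4 ± 1.82 to 0.197 ± 0.0900 CPM (-6.16 ± 0.26) and rose in ILC2s (4.86 ± 0.11). Hif1a itself rose in ILC2s from 244 ± 5.31 to 573 ± 9.40 CPM (1.23 ± 0.038) and in eosinophils stood at 455 ± 35.3 to 450.3 ± 20.1 CPM, which did not pass the test (edgeR adjusted p = 0.89).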
